A study of Mus musculus with 19 samples.

How the data were processed

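Messenger RNA was profiled by bulk RNA-seq in the medial prefrontal cortex of wild-type mice. Total RNA was extracted with TRIzol, transcripts with a poly(A) tail were captured on oligo(dT) beads, and strand-marking Illumina libraries were prepared by ligation, per the labels' protocols. The deposited table holds whole-number read counts per gene, not normalized, for 57010 genes in 19 libraries, and none of its columns was left unmatched to a sample. Per the submitters' processing notes, the tools used upstream were fastp, HISAT2, StringTie, RSEM and DESeq2, with no versions. The deposited counts carry the name of another tool, featureCounts, which is not in that list, and its settings are not given. Whether the counting used strand is also not given, so overlapping and antisense genes cannot be told apart in these values. The genome build is not given either. Of 52029 gene identifiers shared with the GRCm38 annotation at hand, 2.81% (1460) had the same start, so coordinates are printed as the deposited table gives them and none was taken from that annotation.

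The libraries fell into 4 groups by their labels. Control mice (n = 4; the labels number these replicates 1, 2, 4 and 5) received saline by gavage for 8 days and saline by intraperitoneal injection for 5 days. LPS mice (n = 5) received bacterial lipopolysaccharide at 1 mg/kg in place of the injected saline. Sedanolide mice (n = 5) received sedanolide, a phthalide found in celery seed oil, by gavage at 20 mg/kg. The last group (n = 5), called co-treated below, received both, with gavage starting 3 days before the first LPS injection. Nothing in the labels says that replicates of a group came from separate animals, so p-values measure only the spread between these samples. A control replicate 3 was not analysed here. Library totals ranged from 19.08 M to 24.32 M counts (mean 22.23 M ± 1.53, SD), and per-gene values are given as CPM, counts per M of the library total (M = mega) scaled by the library factors below.

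Counts were tested with edgeR 4.0.16 in R 4.3.3: trimmed-mean (TMM) library factors, the default expression filter by group, which left 17757 genes, and the quasi-likelihood test with robust dispersion, all 19 libraries sharing 1 model with a mean per group. The test was two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, and a gene was called at an adjusted p below 0.05. Log2 fold changes are printed with a standard error (SE), taken as the absolute log2 change over the square root of the F statistic. The comparisons were LPS against control, sedanolide against control, co-treated against LPS, co-treated against control, and the difference between the sedanolide change with LPS and without it (the interaction). Groups, tests, gene lists, the naming rule and the first set of alternatives were fixed before the data were examined.

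A set of 37 gene lists of pathways, cell types and brain regions was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, which compares a list's genes with all other genes. Adjustment was over the lists of each comparison, and each test was repeated with an estimated correlation and with fry. Some lists share members, so their calls are not independent. Lcn2 is in the neutrophil, reactive astrocyte, endothelial LPS-response and glucocorticoid lists, and Icam1 in the cytokine and endothelial LPS-response lists. For members of a list, calls over all genes are given with calls adjusted over the list alone. Genes are named by a fixed rule: in each comparison except co-treated against control, the 10 genes called higher and the 10 called lower with the largest fold change among protein-coding, named genes of mean log2 CPM of at least 1. Added to these were a panel of 22 genes of complement, glia, glycolysis and stress, up to 4 members of each called list with the smallest p in its direction, and the most highly expressed member of each cell type or region list. Genes with near-identical copies, such as the globin, Xlr3 and H2 class I genes, are uncertain where counting could split reads between copies.

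Alternatives were other library factors (RLE and upper quartile), no expression filter, a filter of 1 CPM in 4 libraries, a minimum fold of 1.5, DESeq2 1.42.0, limma-voom with sample weights, only the groups compared, the replicate number as a block, and leaving out each library in turn. After the libraries were seen to differ in olfactory bulb transcripts, fits were added with an index of 4 bulb markers (Eomes, Cdhr1, Doc2g and Shisa3) as a covariate, in the 12 libraries with Cdhr1 under 20 CPM, and in the 7 above it. Fits with offsets for transcript length and GC content were added likewise. DESeq2 left no adjusted p for 13363 to 20701 genes, which were not counted as calls. The share of genes moving in opposite directions in a pair of comparisons was set against 20 simulated co-treated groups with no change. Principal components were computed from the 1000 most variable genes. Permutation tests were run in R, and plots used matplotlib 3.10.9 in Python 3.11.15.

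The test was checked on simulated counts with 200 changed genes among about as many genes as were tested. Of genes changed 1.5-fold, 49.5% were recovered in LPS against control (17483 genes), 45% in sedanolide against control (17488), 54% in co-treated against LPS (17485) and 11% in the interaction (17485). At 2-fold these shares were 85%, 84.5%, 87% and 67.5%, and false calls made up at most 7.53% of calls in any simulation. Samples were also checked for repeated libraries by a chi-square statistic over genes with at least 40 counts in a pair. The closest pair, co-treated replicates 1 and 3, had a mean statistic of 2.6 per gene (median 0.859). Other pairs of that group had means of 6.32 to 65.7 (medians 1.16 to 6.3), and sampling noise gives 1 on average. The pair was kept as separate samples, though a shared animal or RNA cannot be ruled out. Tnf, a panel gene, was below the expression filter, with 9 counts in all control libraries, 19 in LPS, 4 in sedanolide and 7 in co-treated libraries. Some genes chosen by the naming rule are not reported here.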

Results

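The prefrontal transcriptome was compared in 4 groups of mice: saline controls (n = 4), mice injected with LPS (n = 5), mice gavaged with sedanolide (n = 5) and co-treated mice given both (n = 5). LPS is a bacterial cell wall component that is used to induce systemic inflammation and depressive-like behaviour in rodents, and the study asks whether sedanolide acts on complement C3a and its receptor and on microglial glycolysis. Library totals were close between groups, with means of 22.4 M counts ± 1.55 (SD) in controls, 21.05 M ± 2.04 in LPS, 22.69 M ± 1.21 in sedanolide and 22.81 M ± 0.82 in co-treated libraries. The mean share of counts from mitochondrially encoded genes was 9.43% ± 1.87 in controls, 9.1% ± 1.6 in LPS, 8.78% ± 1.57 in sedanolide and 9.62% ± 2.41 in co-treated libraries. Between 23844 and 25620 genes had at least 1 count per library.

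The libraries differed most in transcripts of the olfactory bulb, a region in front of the prefrontal cortex. The first principal component held 47.3% of the variance of the most variable genes, and its leading genes were Ms4a15, Eomes, S100a5, Omp, Shisa3 and Doc2g, of which Eomes, Shisa3 and Doc2g mark projection neurons of the bulb. Cdhr1, a cadherin of the same neurons, stood at 57.658 to 444.762 CPM in 7 libraries (control replicates 1 and 5, LPS replicates 2, 3 and 4, sedanolide replicates 3 and 4) and at 2.288 to 9.917 CPM in the other 12, among them all 5 co-treated libraries. These sets are called bulb-rich and bulb-poor libraries below. Because no co-treated library was bulb-rich, the counts and part of the results are also given in bulb-poor libraries.

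**Figure D1:**
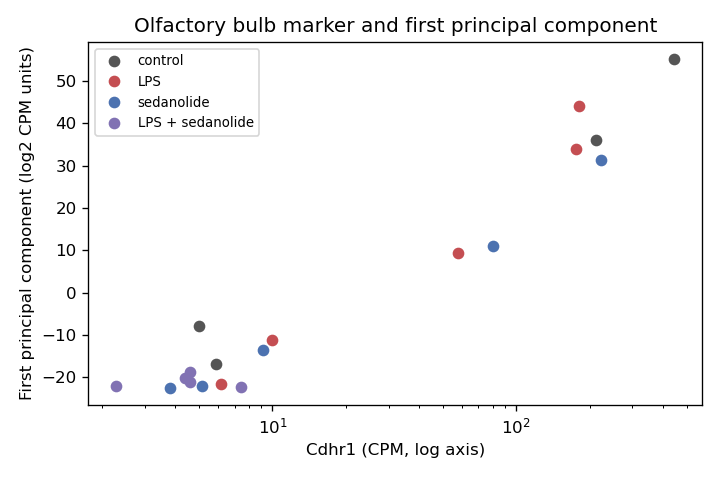
Cdhr1 in CPM on a log axis against the first principal component of the 1000 most variable genes, 1 point per library, coloured by group. The 7 libraries with 57.658 to 444.762 CPM lie apart from the 12 with 2.288 to 9.917 CPM, which include all 5 co-treated libraries.

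The comparison of LPS with control asked what repeated LPS injection changed in the cortex, and its largest changes were higher expression of innate immune genes. The gene with the largest change was Saa3, an acute-phase serum amyloid, which rose by 11.48 on the log2 scale (SE 0.37, adjusted p = 2.61e-13), from 0.043 CPM ± 0.051 (SD, n = 4) to 139 CPM ± 40.1 (SD, n = 5). The chemokine gene Ccl5 rose by 7.07 (SE 0.49), from 0.141 CPM ± 0.109 to 20.8 CPM ± 9.97. Lcn2, encoding the siderophore-binding protein lipocalin 2, rose 38.5-fold, and C3, the central complement component, rose 13.2-fold, from 0.918 CPM ± 0.513 to 12.1 CPM ± 2.35. Fos, a neuronal activity-regulated transcription factor gene, fell to 0.312 of the control level, from 102 CPM ± 27 to 32 CPM ± 12.5. For each of these genes all 5 LPS libraries lay on the same side of all 4 control libraries. In the table's coordinates, Saa3 (ENSMUSG00000040026) lies on chromosome 7 from 46361422 to 46365124, Ccl5 (ENSMUSG00000035042) on chromosome 11 from 83416604 to 83421344 and Lcn2 (ENSMUSG00000026822) on chromosome 2 from 32274645 to 32278264. C3 (ENSMUSG00000024164) lies on chromosome 17 from 57510970 to 57535136 and Fos (ENSMUSG00000021250) on chromosome 12 from 85520664 to 85524047, with the genome build not given.

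In all, 1938 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1504 higher and 434 lower after LPS, and 678 of the higher but 28 of the lower changed more than 2-fold. The division depended on the model, with 1260 higher and 829 lower with offsets for transcript length and GC content, and 1749 higher and 2129 lower with the bulb index as well. Among genes of mean log2 CPM of at least 1, the remaining ones of largest rise were leukocyte or microglial genes: Fcgr4, an activating Fc receptor (4.43, SE 0.33), Aoah, whose product deacylates LPS (3.79), and Itgal, an integrin of leukocytes (3.76). They were followed by the calprotectin subunits S100a9 (3.74) and S100a8 (3.71), and Myo1g, a myosin of blood cells (3.38). The largest falls besides Fos were those of the globin gene Hba-a2 (-1.95), Xlr3b (-1.86), the matricellular gene Ccn1 (-1.54), the activity-regulated genes Egr2 (-1.47), Nr4a1 (-1.43), Dusp1 (-1.42) and Arc (-1.21), and the neuropeptide genes Cartpt (-1.25) and Cort (-1.10). Of 91 named genes called here, 87 stayed past the threshold in each of the 19 fits that left out a library. The calls of Xlr3b (6 fits, adjusted p up to 0.0942), Cartpt (0.0648 without control replicate 5) and Gfap (0.072, 0.0591 and 0.055 without control replicates 4 and 5 and LPS replicate 2) were among those lost. In bulb-poor libraries alone 848 genes were called and in bulb-rich libraries alone 761. With the bulb index in the model 3433 were called.

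Complement and microglial genes rose together after LPS. Of 23 complement genes tested, 14 rose and none fell (16 and 1 when adjusted over the list alone; median log2 change 1.29, camera adjusted p = 3.51e-23). C3ar1, encoding the C3a receptor (ENSMUSG00000040552, chromosome 6 from 122824097 to 122833120), rose by 2.04 (SE 0.20, adjusted p = 6.86e-07), from 3.65 CPM ± 1.18 to 15.1 CPM ± 2.31. C1qa rose by 1.73 (SE 0.13), C1qc by 1.72, C4b by 2.08 and the complement receptor integrin Itgb2 by 2.34. Of 25 genes of activated microglia, 20 rose (21 adjusted over the list alone; median 1.48, camera adjusted p = 1.04e-46), among them Itgax (3.23), Cd14, a co-receptor for LPS (2.04), Fcgr3 (1.76), Cd68 (1.59, SE 0.13) and Aif1, which encodes the microglial marker Iba1 (1.53, SE 0.27). Of 16 genes of homeostatic microglia, 10 rose (12 adjusted over the list alone; median 0.57, camera adjusted p = 3.71e-12, with adjusted p = 0.0741 with an estimated correlation), including the receptor genes Csf1r (1.41) and Cx3cr1 (1.09), and Tmem119 (0.99, SE 0.13).

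Cytokine, antigen-presentation and interferon genes rose as well. Il1b, encoding interleukin-1 beta, rose by 2.84 (SE 0.38), the inflammasome gene Nlrp3 by 2.19, the receptor gene Tlr2 by 2.10 and Nfkb2 by 1.38, within a list of 26 cytokine and NF-kB genes of which 17 rose (19 adjusted over the list alone; camera adjusted p = 9.82e-19). Of 17 antigen-presentation genes 9 rose (10 adjusted over the list alone; 3.99e-10), with H2-K1 at 2.01, H2-Q4 at 1.60, Ctss at 1.59 and H2-DMb1 at 1.29. Of 36 interferon-response genes 13 rose (18 adjusted over the list alone; camera adjusted p = 6.83e-10, but adjusted p = 0.133 with an estimated correlation), among them Tap1 (1.61), the transcription factor gene Irf7 (1.44), Psmb9 (1.34) and Gbp5 (1.24). Of 27 reactive astrocyte genes 16 rose (19 adjusted over the list alone; 1.12e-19), including Serpina3n (2.71, SE 0.30), H2-D1 (2.18) and H2-T23 (0.97). Gfap, the intermediate filament of astrocytes, rose by 1.38 (SE 0.37, adjusted p = 0.0197), whereas none of 15 astrocyte identity genes was called (camera adjusted p = 0.858) and the most abundant of them, Slc1a2, stood at 0.07 (SE 0.20).

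Genes of blood vessels and of circulating leukocytes also rose. Of 20 endothelial identity genes 18 rose (20 adjusted over the list alone; median 0.86, camera adjusted p = 6.09e-25), including the tight-junction gene Cldn5 (0.99), Tie1 (1.29), Esam (1.17) and the amino acid transporter gene Slc7a5 (1.02). Of 22 genes that respond to LPS in endothelium 14 rose (15 and 1 lower when adjusted over the list alone; 9.17e-11), with Vwf, encoding von Willebrand factor, at 2.56 (SE 0.25), the adhesion molecule gene Icam1 at 1.95 and Ly6a at 1.08. Of 12 pericyte and smooth muscle genes 5 rose (6 adjusted over the list alone; 6.01e-06, adjusted p = 0.0817 with an estimated correlation), among them Abcc9 (1.18), Notch3 (1.01), Kcnj8 (0.95) and Rgs5 (0.73). Of 12 neutrophil genes 11 rose (11 adjusted over the list alone; median 3.42, camera adjusted p = 3.77e-25), including Cxcr2 (4.48), Mmp9 (2.80) and Csf3r (2.15). Of 14 monocyte and lymphocyte genes 11 rose (11 adjusted over the list alone; 1.34e-10), including the cytotoxic granule gene Gzma (4.48), Nkg7 (3.24), Chil3 (3.07), Igkc (2.39) and Ighm (1.10). Of 13 border macrophage genes 3 rose, Ms4a7 (1.82), Stab1 (1.65) and Maf (0.67), and 1 fell (5 and 1 when adjusted over the list alone; 0.0134). That call had an adjusted p of 0.533 with an estimated correlation and was lost without control replicate 4 (0.169) and without LPS replicate 4 (0.0536).

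Genes of glycolysis rose in part. Hk2, a hexokinase isoform (ENSMUSG00000000628, chromosome 6 from 82702006 to 82751435), rose by 1.58 (SE 0.14, adjusted p = 2.76e-07), from 5.4 CPM ± 1.46 to 16.1 CPM ± 1.06. The glucose transporter gene Slc2a1 (ENSMUSG00000028645, chromosome 4 from 118965908 to 118995180) rose by 1.23 (SE 0.14, adjusted p = 4.34e-06), from 123 CPM ± 28.9 to 289 CPM ± 53.3, and all 5 LPS libraries exceeded all controls for both genes. Hk3, the hexokinase of myeloid cells, rose by 1.67, the lactate transporter gene Slc16a1 by 1.20 and Pfkfb3, encoding an activator of phosphofructokinase, by 0.58 (SE 0.09). Pkm (-0.02, SE 0.08, adjusted p = 0.934), Ldha (-0.02, SE 0.14, 0.949) and Hif1a (0.01, SE 0.09, 0.971) were not called. Of the 31 entries of the glycolysis list 6 rose (6 and 1 lower when adjusted over the list alone; median 0.03, mean 0.24, camera adjusted p = 0.0207), with adjusted p = 0.255 with an estimated correlation. The median was -0.0115 without control replicate 2, 0.0805 without control replicate 4, and -0.0727 with offsets for length and GC content (adjusted p = 0.272), so only the members called are given a direction. The 35 nuclear genes of oxidative phosphorylation shifted lower as a list (median -0.14, camera adjusted p = 0.00168, adjusted p = 0.578 with an estimated correlation), none of them was called over all genes or over the list alone, and Ndufb5 (-0.29, SE 0.12, 0.147) had the smallest p.

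Immediate early genes, which neurons transcribe rapidly upon activity, fell as a group after LPS, with 15 of 29 lower and none higher (21 and 2 when adjusted over the list alone; median -0.70, camera adjusted p = 1.33e-17). This list held in bulb-poor libraries (median -0.66) and in bulb-rich libraries (-0.87). Of 22 cholesterol synthesis genes 12 fell (16 adjusted over the list alone; median -0.44, camera adjusted p = 1.03e-09, adjusted p = 0.158 with an estimated correlation), among them Idi1 (-1.05), Insig1 (-0.87), Msmo1 (-0.86) and Cyp51 (-0.67). Of 20 inhibitory neuron genes 1 was called lower, and none when adjusted over the list alone (median -0.31, camera adjusted p = 0.0256, adjusted p = 0.111 with an estimated correlation). That list call was lost without control replicate 5 (0.0513) or LPS replicate 1 (0.0512). Of 8 erythroid genes only Hba-a2 was called over all genes (1 higher and 6 lower when adjusted over the list alone; median -1.22, camera adjusted p = 0.00168, adjusted p = 0.255 with an estimated correlation). LPS replicate 1 had an erythroid score of -2.924, against -0.855 to 0.871 in the other LPS libraries and 0.651 to 1.01 in controls. The erythroid median was -0.92 without this library and -1.89 without LPS replicate 4, whose score of 0.871 lay within the controls.

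Genes that respond to glucocorticoids or to NRF2 shifted higher as lists. Of 22 glucocorticoid-responsive genes 8 rose and 4 fell (9 and 5 when adjusted over the list alone; median 0.14, camera adjusted p = 0.0253), a call with an adjusted p of 0.349 with an estimated correlation and of 0.108 without control replicate 4. The genes that rose included Galnt15 (2.39), Fkbp5, which encodes a co-chaperone of the glucocorticoid receptor (1.04, SE 0.14), and Zbtb16, a transcription factor gene (1.00, SE 0.16). Of 25 NRF2 target genes 3 rose, Hmox1 (1.23, SE 0.18), Nfe2l2 (0.75) and Ftl1 (0.48), with 3 adjusted over the list alone (camera adjusted p = 0.0163, 0.0817 with an estimated correlation). Nqo1 (-0.10, SE 0.21, adjusted p = 0.818) and the neurotrophin gene Bdnf (-0.11, SE 0.28, 0.861) were not called. In all 21 lists were called, 16 higher and 5 lower. Bulb-poor libraries kept 19 of them, without nuclear oxidative phosphorylation (median -0.0686, adjusted p = 0.339) and border macrophages (0.0318, 0.445). The 10 that held with an estimated correlation were complement (adjusted p = 0.000805), activated microglia (0.000233), reactive astrocytes (0.0144), cytokine and NF-kB (0.00211), antigen presentation (0.0032), endothelial LPS response (0.0472), endothelial identity (0.0144), neutrophils (0.000635), monocytes and lymphocytes (0.000805) and immediate early genes (0.000805).

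**Figure D2:**
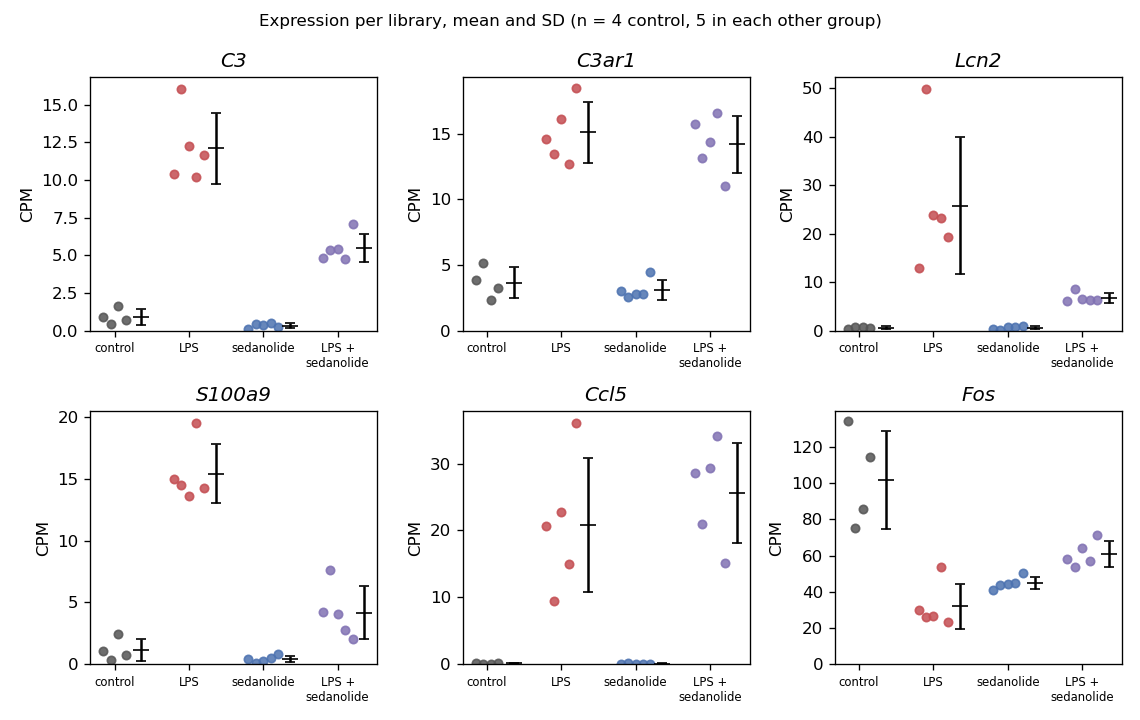
CPM of C3, C3ar1, Lcn2, S100a9, Ccl5 and Fos in each library by group, with the mean and SD. C3 fell from 12.1 CPM ± 2.35 in LPS to 5.49 CPM ± 0.933 in co-treated libraries, while C3ar1 stood at 15.1 CPM ± 2.31 and 14.2 CPM ± 2.18.

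The comparison of co-treated with LPS libraries asked what sedanolide changed in mice given LPS, and neutrophil genes were lower while activity-regulated genes were higher. Arc, whose product acts at the synapse (ENSMUSG00000022602, chromosome 15 from 74540932 to 74544419), rose 2.75-fold (log2 1.46, SE 0.17, adjusted p = 0.000154), from 131 CPM ± 36.1 to 360 CPM ± 44.1 (SD, n = 5 each). Egr2 rose 2.56-fold (1.36, SE 0.11, adjusted p = 3.81e-06). Lcn2 fell to 0.264 of its level with LPS alone (-1.92, SE 0.29, adjusted p = 0.00199), from 25.8 CPM ± 14.1 to 6.8 CPM ± 1. Itgal fell to 0.215 (-2.22, SE 0.26, adjusted p = 0.000165). C3 fell to 0.453 (-1.14, SE 0.24, adjusted p = 0.0177), and for all 5 of these genes every co-treated library lay outside the range of the LPS libraries. C3ar1 did not pass the test (-0.09, SE 0.17, adjusted p = 0.795).

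Of 350 genes called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 51 were higher and 299 lower in co-treated than in LPS libraries. The division was 191 and 352 with offsets for transcript length and GC content, 296 and 431 with the bulb index as well, and 14 and 21 in bulb-poor libraries. The other genes of largest rise were Fos (0.93, SE 0.19), Gpr3, a receptor that raises cyclic AMP (0.93, SE 0.11), the phosphatase genes Dusp1 (0.85) and Dusp6 (0.79), Junb (0.84), Klf10 (0.81), Dyrk3 (0.79) and Nr4a1 (0.75). The other largest falls were those of Prss56 (-4.28, SE 1.07), Prg4, encoding lubricin (-2.78, SE 0.70), Lbp, encoding LPS-binding protein (-2.36, SE 0.35), S100a9 (-1.88, SE 0.36), the lipid-droplet gene Plin4 (-1.69), Vwf (-1.64, SE 0.22), the gelatinase gene Mmp9 (-1.61) and the coagulation factor gene F13a1 (-1.56). Of 51 named genes called here, 22 stayed past the threshold in all 19 fits that left out a library, among them Arc, Egr2, Gpr3, Dusp1, Junb, Dusp6, Lbp, Itgal, Lcn2, S100a9, Plin4, Vwf and Mmp9. Selp was tested in 15 of these fits and called in each. The calls of Prg4 (lost in 16 fits, adjusted p up to 0.2), Prss56 (13 fits, 0.143), Dyrk3 (12 fits, 0.142), F13a1 (7 fits, 0.0966) and Nr4a1 (6 fits, 0.0864) were lost in part of these fits. C3 was lost without LPS replicate 2 (0.0599) and without co-treated replicates 1 (0.0609) or 3 (0.0548), Fos without LPS replicate 2 (0.0594) or co-treated replicate 5 (0.0556), and Klf10 without LPS replicate 2 (0.0599).

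The count of 350 depended on single libraries. It was 141 without LPS replicate 2, 211 without LPS replicate 3, 220 without LPS replicate 4, 143, 196, 149 and 157 without co-treated replicates 1, 2, 3 and 5, but 590 without LPS replicate 5 and 548 and 551 without control replicates 1 and 4. In bulb-poor libraries 35 genes were called, with Itgal at -1.87 (adjusted p = 0.00615), Lcn2 at -1.22 (0.0318), Vwf at -1.36 (0.0409), Arc at 1.43 (0.0133), Fos at 1.21 (0.00149) and Egr2 at 1.47 (0.000128) among them. There C3 stood at -0.99 (adjusted p = 0.195), S100a9 at -1.79 (0.187) and Prg4 at 0.03. With the bulb index in the model C3 fell by 1.11 (adjusted p = 0.0113).

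Of 12 neutrophil genes 8 fell in co-treated mice (11 adjusted over the list alone; median -1.61, camera adjusted p = 8.27e-19), among them Retnlg (-2.90, SE 0.36) and the granule protein gene Ltf (-2.15, SE 0.40). Of 14 monocyte and lymphocyte genes 3 fell, Plac8 (-3.19), Chil3 (-2.30) and Igkc (-1.60), with 3 adjusted over the list alone (0.00209, adjusted p = 0.102 with an estimated correlation). Of 22 endothelial LPS-response genes 8 fell (16 and 1 higher when adjusted over the list alone; median -0.69, camera adjusted p = 2.52e-10, adjusted p = 0.102 with an estimated correlation), including Selp, encoding P-selectin (-3.94, SE 0.62), Icam1 (-1.07) and Ly6a (-0.81). Of 20 endothelial identity genes 3 fell, Eng (-0.80), Tie1 (-0.78) and Esam (-0.43), with 11 adjusted over the list alone (1.3e-09, adjusted p = 0.216 with an estimated correlation). Of 12 pericyte and smooth muscle genes 2 fell, the contractile gene Myh11 (-1.41) and Notch3 (-0.70), with 9 adjusted over the list alone (1.3e-06, adjusted p = 0.131 with an estimated correlation). Plac8 lost its call without co-treated replicate 1 (0.0513), Eng without LPS replicate 2 (0.0525) or co-treated replicate 1 (0.0514), and Icam1 without LPS replicate 2 (0.0549) or co-treated replicates 1 (0.0545) or 3 (0.0567). Igkc (7 fits), Esam (9), Myh11 (15) and Notch3 (6) were lost more often, with adjusted p up to 0.141.

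Of 27 reactive astrocyte genes 9 fell (20 adjusted over the list alone; median -0.68, camera adjusted p = 6.52e-15, adjusted p = 0.102 with an estimated correlation), with Emp1 at -1.05 and Fkbp5 at -0.74 (SE 0.13, adjusted p = 0.00422). Vim, encoding vimentin, fell by 1.00 (SE 0.18). Emp1 lost its call without LPS replicate 2 (0.0525) or co-treated replicates 1 (0.0541) or 5 (0.0534). Serpina3n fell by 1.03 (SE 0.26, adjusted p = 0.049), a call lost in 13 of the 19 fits that left out a library (adjusted p up to 0.174), and Gfap was not called (-0.47, SE 0.34, 0.433). Of 15 astrocyte identity genes none was called over all genes or over the list alone, with Slc4a4 at -0.49 (SE 0.20, 0.194) (median -0.19, camera adjusted p = 0.0127, 0.459 with an estimated correlation). That list call was lost without LPS replicate 1 (0.0506) or co-treated replicate 5 (0.108).

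Of 23 complement genes 3 fell in co-treated mice, C3, C1s1 (-0.69, SE 0.17) and Itgb2 (-0.56, SE 0.14), with 10 adjusted over the list alone (median -0.44, camera adjusted p = 7.34e-06, 0.143 with an estimated correlation). The list median ran from -0.531 to -0.266 when single libraries were left out. C1s1 and Itgb2 lost their calls in 9 and 11 of the 19 fits that left out a library (adjusted p up to 0.107 and 0.159). C1qa (-0.13, SE 0.11, adjusted p = 0.523) and C4b (-0.88, SE 0.38, 0.21) were not called. Microglial lists did not pass the threshold in all libraries: 2 of 25 activated microglia genes fell (2 adjusted over the list alone; median -0.07, camera adjusted p = 0.0727) and none of 16 homeostatic genes was called (median 0.01, mean -0.04, camera direction higher, adjusted p = 0.833). In bulb-poor libraries both lists passed as lower, at -0.18 for activated (adjusted p = 0.0127) and -0.13 for homeostatic microglia (0.0343). Aif1 stood at 0.01 (SE 0.24, adjusted p = 0.983), Cd68 at -0.06 (SE 0.12, 0.787), Tmem119 at -0.12 (SE 0.12, 0.584) and Il1b at -0.39 (SE 0.30, 0.467).

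Among glycolysis genes only Slc2a1 was called in co-treated against LPS libraries, over all genes and adjusted over the list alone. It fell by 0.59 (SE 0.13, adjusted p = 0.0209), from 289 CPM ± 53.3 to 192 CPM ± 16.8, and all 5 co-treated libraries lay below all 5 LPS libraries. The call was lost without LPS replicates 1 (0.0526) or 2 (0.0723), without co-treated replicates 1, 2, 3 or 5 (0.0612, 0.0649, 0.0569 and 0.0597), and in bulb-poor libraries (-0.61, adjusted p = 0.222). Endothelial identity genes moved as Slc2a1 did (median 0.862 after LPS, -0.361 here), and bulk tissue cannot tell in which cells Slc2a1 changed. Hk2 (-0.20, SE 0.13, adjusted p = 0.377), Ldha (0.37, SE 0.13, 0.145), Pkm (0.17, SE 0.07, 0.209), Pfkfb3 (-0.02, SE 0.08, 0.913) and Hif1a (-0.08, SE 0.08, 0.578) were not called. The list of 31 entries had a median of 0.05 (camera adjusted p = 0.125). Bdnf (0.57, SE 0.26, 0.238), Nqo1 (-0.37, SE 0.20, 0.304) and Hmox1 (-0.52, SE 0.16, 0.0948) were not called either.

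Immediate early genes rose in co-treated against LPS libraries, with 10 of 29 higher and none lower (13 adjusted over the list alone; median 0.30, camera adjusted p = 8.27e-19). The median was 0.49 in bulb-poor libraries. Of 22 cholesterol synthesis genes Cyp51 (0.54) and Insig1 (0.47) rose, with 12 adjusted over the list alone (median 0.29, camera adjusted p = 3.88e-10, 0.216 with an estimated correlation). Of 26 heat shock and unfolded protein genes the chaperone genes Dnajb1 (0.47) and Hsph1 (0.45) rose and 1 gene fell (4 and 1 adjusted over the list alone; 0.000484, 0.223 with an estimated correlation). Without single libraries Cyp51 (LPS replicate 2, 0.0503; co-treated replicate 1, 0.0545), Insig1 (LPS replicate 3, 0.0544; co-treated replicate 1, 0.0551) and Dnajb1 (LPS replicates 2 and 4, 0.0691 and 0.0507) lost their calls, and Hsph1 lost its call in 10 fits.

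Further lists shifted with few or no called members. Cytokine and NF-kB genes shifted lower (1 of 26 called, Icam1; 5 adjusted over the list alone; camera adjusted p = 0.000676, 0.223 with an estimated correlation). Interferon genes did so too (0 of 36; 2 adjusted over the list alone; median -0.24, 0.000676, 0.452 with an estimated correlation). The same held for antigen-presentation genes (0 of 17; 1 adjusted over the list alone; 0.0085, 0.223 with an estimated correlation) and NRF2 targets (0 of 25; 4 adjusted over the list alone; 0.015, 0.143 with an estimated correlation, and 0.0563 without LPS replicate 1). Nuclear oxidative phosphorylation genes shifted higher (0 of 35, and 0 adjusted over the list alone; median 0.11, camera adjusted p = 0.00136, 0.523 with an estimated correlation). Of the 20 lists called, 4 were higher and 16 lower, and only immediate early genes (adjusted p = 0.00163) and neutrophils (0.00357) held with an estimated correlation. Bulb-poor libraries kept 18 of the 20.

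Lists of tissue around the cortex shifted lower at the preset correlation in co-treated than in LPS libraries, the group with 3 bulb-rich libraries. Of 18 genes of olfactory areas and other forebrain regions, 1 fell, Synpo2 (-0.94, SE 0.17), with 12 adjusted over the list alone (median -0.84, camera adjusted p = 1.29e-06, adjusted p = 0.223 with an estimated correlation; -0.43 in bulb-poor libraries). Of 17 meningeal and fibroblast genes none fell over all genes and 14 did adjusted over the list alone (median -1.32, 1.47e-06, adjusted p = 0.325 with an estimated correlation), and in bulb-poor libraries the median was 0.21 (adjusted p = 0.148). Of 13 choroid plexus and ependymal genes F5 (-1.31, SE 0.26) and Clic6 (-2.36, SE 0.59) fell (6, and 1 higher, adjusted over the list alone; median -1.31, 0.00754, adjusted p = 0.255 with an estimated correlation; -0.91 in bulb-poor libraries). Of 13 border macrophage genes 5 fell (8 adjusted over the list alone; median -1, 2.03e-07, adjusted p = 0.222 with an estimated correlation, and -0.286 with adjusted p = 0.0927 in bulb-poor libraries), among them Cbr2 (-1.38), Ms4a7 (-1.16) and Stab1 (-0.74). Clic6 lost its call in 12 of the 19 fits that left out a library, Cbr2 in 8, Ms4a7 in 10 and Stab1 in 6 (adjusted p up to 0.163).

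**Figure D3:**
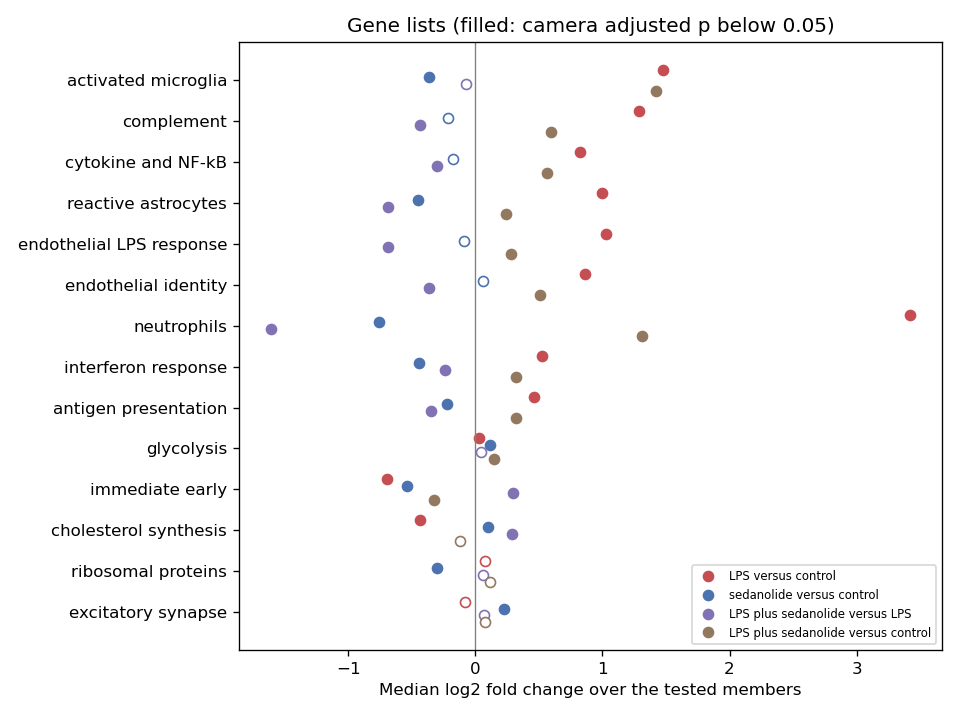
Median log2 fold change of 14 gene lists in the 4 comparisons between groups, with filled points where camera's adjusted p was below 0.05. Immediate early genes lay at -0.70 after LPS and at 0.30 in co-treated against LPS libraries, and neutrophil genes at 3.42 and -1.61.

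The comparison of LPS against control and that of co-treated against LPS share the LPS libraries, which by itself favours opposite signs. Of the 1938 genes called after LPS, 1660 (85.7%) had the opposite sign in co-treated against LPS libraries, and 250 of these were called there, against 2 called in the same direction. The share was 88.3% of genes higher and 76.5% of genes lower after LPS. In 20 simulations of an unchanged co-treated group the share averaged 64.3% (63.2% to 66.2%), over the 2893 genes called there on average (2799 to 2973) and so over a larger set than the 1938 genes observed. Counts were drawn for each gene independently, so the simulated ranges leave out bulb differences and other variation that genes share between libraries. Splitting the LPS libraries into parts of 2 and 3, 1 part for each comparison, gave 80.2% on average (58.6% to 93.9% over 20 splits). The covariance of the log2 changes across all tested genes was -0.0599, against -0.0332 on average in the simulations. With the LPS libraries split it averaged -0.01 and took both signs (-0.0926 to 0.174). With the bulb index in the split fits it averaged -0.0803 and was negative in all 20 (-0.102 to -0.0215). In these fits the share of opposite signs averaged 79.4%, from 48.9% to 90.3%. With the split, 95.3 genes on average were called in opposite directions and 4 in the same direction. Among the genes in question the median ratio of the change in co-treated against LPS libraries to the LPS change was -0.343, against -0.0742 on average in the simulations and -0.25 with the split (-0.358 to -0.0784). It was -0.253 with the bulb index in the split fits, from -0.413 to 0.0115.

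Co-treated mice still differed widely from controls, a comparison that asked how far the co-treated state stood from the untreated state. C3 was 5.99-fold higher (log2 2.58, SE 0.30, adjusted p = 1.12e-05), C3ar1 3.87-fold (1.95, SE 0.20, 2.7e-06), C1qa 3.02-fold (1.60, SE 0.13, 1.24e-07) and Lcn2 10.2-fold (3.34, SE 0.39, 1.2e-05), and for C3, C3ar1 and Lcn2 all 5 co-treated libraries lay above all 4 controls. Hk2 (1.38, SE 0.14), Pfkfb3 (0.56, SE 0.09), Slc2a1 (0.64, SE 0.14, adjusted p = 0.00618) and Il1b (2.45, SE 0.39) were higher too. Aif1 (1.54), Cd68 (1.52), Tmem119 (0.87), Serpina3n (1.68) and Hmox1 (0.70, adjusted p = 0.0151) were also called, whereas C4b (1.20, SE 0.41, 0.0669), Gfap (0.91, SE 0.36, 0.11), Ldha (0.35, SE 0.14, 0.111), Pkm (0.16, SE 0.08, 0.199) and Fkbp5 (0.31, SE 0.13, 0.138) were not.

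In this comparison edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1965 genes, 1133 higher and 832 lower, of which 804 and 184 were called in the same direction after LPS alone. Activated microglia genes were higher (17 of 25; 17 higher and 2 lower adjusted over the list alone; median 1.42, camera adjusted p = 4.61e-45). So were complement genes (11 of 23; 12 adjusted over the list alone; 0.60, 1.23e-13) and cytokine and NF-kB genes (12 of 26; 16 adjusted over the list alone; 0.57, 9.04e-12). Neutrophil genes (6 of 12; 7 adjusted over the list alone; 1.31, 3.54e-08) and monocyte and lymphocyte genes (5 of 14; 6 adjusted over the list alone; 0.77, 3.51e-06) were higher too. Antigen-presentation genes followed (7 of 17; 10 adjusted over the list alone; 0.32, 3.52e-06). These 6 lists held with an estimated correlation (adjusted p = 0.000453, 0.0163, 0.0241, 0.0464, 0.0163 and 0.0394). Glycolysis genes were called higher (7 of 31; 9 higher and 1 lower adjusted over the list alone; median 0.15, 0.000171, 0.105 with an estimated correlation).

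Other lists differed between co-treated and control libraries at the preset correlation only. Homeostatic microglia genes were higher (10 of 16; 15 adjusted over the list alone; camera adjusted p = 6.1e-14, adjusted p = 0.0703 with an estimated correlation), with Csf1r at 1.28. Endothelial identity genes were higher as well (13 of 20; 16 adjusted over the list alone; 4.13e-11, adjusted p = 0.166 with an estimated correlation). So were reactive astrocyte genes (8 of 27; 12 higher and 3 lower adjusted over the list alone; 3.59e-05, adjusted p = 0.342 with an estimated correlation) and interferon genes (7 of 36; 11 adjusted over the list alone; 8.42e-05, adjusted p = 0.462 with an estimated correlation). Endothelial LPS-response genes had a median of 0.28 (0.0116, adjusted p = 0.484 with an estimated correlation), a call lost without control replicate 4 (0.192). Immediate early genes stayed lower than in controls (6 of 29 lower, 3 higher; 11 and 3 adjusted over the list alone; median -0.32, 0.0148, adjusted p = 0.342 with an estimated correlation). This call, 1 of 17, was the only one lost in bulb-poor libraries (-0.103, adjusted p = 0.228). Meningeal (-1.25, 9.28e-05, 0.484 with an estimated correlation), olfactory (-0.92, 0.00245, 0.484 with an estimated correlation), erythroid (-1.38, 0.00541, 0.425 with an estimated correlation) and deep-layer genes (-0.24, 0.00851, 0.223 with an estimated correlation) were lower. The deep-layer call was lost without control replicate 4 (0.12).

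The count of 1965 genes in co-treated against control was 924 and 876 without control replicates 1 and 5, and 1278, 1228 and 1230 without co-treated replicates 1, 3 and 4. In bulb-poor libraries 615 genes were called, and 1110 with the bulb index in the model. The division of 1133 higher and 832 lower depended on the fit as well. It was 715 and 209 without control replicate 1, 795 and 315 with the bulb index, 475 and 140 in bulb-poor libraries, 686 and 268 with replicate number as a block, and 985 and 968 with upper-quartile scaling.

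The comparison of sedanolide with control asked what the compound changed without LPS, and fewer genes were called than after LPS. Zbtb16 rose by 1.03 (SE 0.16, adjusted p = 0.00417), from 17 CPM ± 4.87 (SD, n = 4) to 34.6 CPM ± 2.92 (SD, n = 5), and Xdh, encoding the purine-degrading enzyme xanthine dehydrogenase, by 1.01 (SE 0.16, 0.00585), from 4.2 CPM ± 1.06 to 8.48 CPM ± 0.739. The kinase gene Sik2 rose by 1.01 (SE 0.15, 0.00336), Sox18, an endothelial transcription factor gene, by 1.00 (SE 0.17, 0.00585) and the clock gene Per2 by 0.72 (SE 0.11, 0.00311). Fos fell by 1.19 (SE 0.20, 0.00585), from 102 CPM ± 27 to 45 CPM ± 3.47, Ccn1 by 1.53 (SE 0.27, 0.00597), Ccn2 by 1.46 (SE 0.24, 0.00585), Dusp1 by 0.90 (SE 0.15, 0.00585) and the interferon-induced gene Ifi27 by 0.64 (SE 0.12, 0.00761). These were the 10 of 50 named calls that stayed past the threshold in all 19 fits that left out a library, and for Zbtb16, Xdh, Sik2, Fos and Ccn1 all 5 sedanolide libraries lay on the same side of all 4 controls.

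In all, 943 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 568 higher and 375 lower, and 15 and 65 of them changed more than 2-fold. The count did not hold across fits: it was 440 and 97 without control replicates 1 and 5, 624, 207 and 299 without sedanolide replicates 1, 4 and 5, 621 without co-treated replicate 3, and 19 with only the sedanolide and control libraries in the model. In bulb-poor libraries 8 genes were called (2081 at an unadjusted p below 0.05). In bulb-rich libraries edgeR called 0 (3911 at an unadjusted p below 0.05; no other tool was run on this subset). Upper-quartile scaling turned the split of 568 higher and 375 lower into 340 higher and 568 lower. Zbtb16, Xdh, Sik2, Sox18, Per2 and Ifi27 lost their calls with only the sedanolide and control libraries (adjusted p = 0.0574, 0.0577, 0.0658, 0.0561, 0.0561 and 0.0584), with log2 changes of 1.03, 1.01, 1.01, 0.99, 0.72 and -0.64 there.

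The other genes of largest rise after sedanolide were Tmem215 (1.65, SE 0.44), the axon guidance receptor gene Robo3 (1.21), the synaptotagmin gene Syt2 (1.18), Exph5 (1.10), Serinc2 (1.00) and Rnf39 (0.97). The other largest falls were those of Ifi27l2a (-2.06, SE 0.53), Apold1 (-1.97), Fgl2 (-1.72), the class II antigen-presentation genes H2-Aa (-1.69) and H2-Ab1 (-1.55), the transcription factor gene Cebpd (-1.60), the fibroblast proteoglycan gene Dcn (-1.60) and the matricellular gene Thbs1 (-1.47). Each of these 14 calls was lost in 1 to 12 of the 19 fits that left out a library. C3 fell by 1.43 (SE 0.37, adjusted p = 0.0344), from 0.918 CPM ± 0.513 to 0.333 CPM ± 0.169, with 3 of 5 sedanolide libraries below all controls. The call was lost without control replicates 1, 4 or 5 (0.0681, 0.0742 and 0.0815) or sedanolide replicates 1, 4 or 5 (0.0593, 0.0515 and 0.0843). C3ar1 (-0.22, SE 0.20, adjusted p = 0.525), C1qa (0.05, SE 0.12, 0.847), Lcn2 (-0.10, SE 0.46, 0.918), Hk2 (0.14, SE 0.14, 0.569), Slc2a1 (0.35, SE 0.14, 0.125) and Ldha (0.19, SE 0.14, 0.41) were not called.

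Of the lists, 19 were called in sedanolide against control, 13 lower and 6 higher, and 0 held with an estimated correlation. Bulb-poor libraries kept 14 of the 19, without glycolysis (median 0.0676, adjusted p = 0.0882), nuclear oxidative phosphorylation (-0.0875, 0.272), homeostatic microglia (-0.00442, 0.622), monocytes and lymphocytes (-0.669, 0.0882) and cholesterol synthesis (-0.0961, 0.183). Of 36 interferon-response genes 7 fell (17 adjusted over the list alone; median -0.44, camera adjusted p = 6.81e-10, adjusted p = 0.299 with an estimated correlation), among them Gbp6 (-1.82), Ifitm3 (-0.93) and Rtp4 (-0.74). Of 29 immediate early genes 10 fell and 2 rose (17 and 4 adjusted over the list alone; median -0.54, camera adjusted p = 7.24e-07, adjusted p = 0.186 with an estimated correlation), with Btg2 at -1.08. Of 17 antigen-presentation genes 5 fell (6 adjusted over the list alone; 0.00135, adjusted p = 0.299 with an estimated correlation), including H2-Eb1 (-1.45). Of 25 activated microglia genes 3 fell, the oxysterol enzyme gene Ch25h (-2.08), Cd74 (-1.41) and the lysozyme gene Lyz2 (-0.87), with 3 adjusted over the list alone (0.00272, adjusted p = 0.446 with an estimated correlation). Of 27 reactive astrocyte genes Gbp2 fell (-0.60; 3 lower and 1 higher adjusted over the list alone; 0.000226, adjusted p = 0.446 with an estimated correlation). Complement genes were not called as a list (median -0.21, 0.0785). Without control replicate 5 the calls of Gbp6 (0.0527), Ifitm3 (0.0652), Rtp4 (0.0787) and Btg2 (0.0527) were lost, and those of Ch25h, Cd74, Lyz2, Gbp2 and H2-Eb1 were lost in 2 to 4 fits (adjusted p up to 0.108).

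Lists of tissue around the cortex and of circulating leukocytes shifted lower after sedanolide at the preset correlation only, with few or no members called over all genes. Of 17 meningeal and fibroblast genes Dcn and Lum (-1.16) fell (7 adjusted over the list alone; median -1.16, camera adjusted p = 7.71e-06, 0.446 with an estimated correlation; -0.91 in bulb-poor libraries). Of 13 border macrophage genes Ms4a7 fell (-1.45; 7 adjusted over the list alone; 0.000226, 0.446 with an estimated correlation). No member was called over all genes in the next 3 lists. These were the olfactory area list (0 of 18, and 0 adjusted over the list alone; median -0.70, 0.0117, 0.578 with an estimated correlation) and the neutrophil list (0 of 12; 1 lower adjusted over the list alone; -0.76, 0.0301, 0.504 with an estimated correlation). The last was the monocyte and lymphocyte list (0 of 14; 3 lower and 1 higher adjusted over the list alone; -0.85, 0.0301, 0.299 with an estimated correlation). The olfactory call was lost without control replicate 1 (0.149) or sedanolide replicate 1 (0.069). The neutrophil call was lost without control replicate 4 (0.293) or sedanolide replicates 2 (0.172) or 3 (0.0957), and the monocyte and lymphocyte call without the same libraries (0.0571, 0.075 and 0.0787).

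Ribosomal protein genes shifted lower after sedanolide, with 2 of 33 called, among them Rpl8 at -0.25 with SE 0.07 (22 adjusted over the list alone; median -0.30, camera adjusted p = 9.06e-11, adjusted p = 0.446 with an estimated correlation). Nuclear oxidative phosphorylation genes lay lower too, with 0 of 35 called and 0 adjusted over the list alone, and Uqcrb at -0.59 (SE 0.20, adjusted p = 0.0806; median -0.18, camera adjusted p = 2.84e-05, adjusted p = 0.504 with an estimated correlation). Sedanolide replicates 3 to 5 carried this shift, with ribosomal scores (mean log2 CPM of the list after subtracting the mean of each gene) of -0.351, -0.446 and -0.511, while replicates 1 and 2 (-0.09 and -0.022) lay within the controls (-0.138 to 0.137). The oxidative phosphorylation scores divided alike, at -0.215, -0.259 and -0.356 against 0.142 and 0.106. With offsets for transcript length and GC content the medians were -0.17 and -0.0602. Across genes the log2 change after sedanolide correlated with transcript length (Spearman 0.253) and GC content (0.29). GC content also correlated with the change after LPS (0.431), and length and GC content with the interaction (-0.319 and -0.412).

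Of the neuronal lists, 3 were called after sedanolide, and inhibitory neurons (camera adjusted p = 0.917) and neurotrophin and plasticity genes (0.167) were not. Of 26 excitatory synapse genes 5 rose (9 and 1 lower adjusted over the list alone; median 0.23, camera adjusted p = 0.000367, 0.299 with an estimated correlation), among them the scaffold genes Shank3 (0.73), Shank1 (0.59) and Shank2 (0.48) and the synapsin gene Syn1 (0.37). Of 15 upper-layer genes 0 were called, with Lamp5 at 0.59 (SE 0.20, adjusted p = 0.0806; 4 adjusted over the list alone; 0.0117, adjusted p = 0.299 with an estimated correlation). Of 17 deep-layer genes Ccn2, Foxp2 (-0.79) and Lratd2 (-0.67) fell (3 adjusted over the list alone; 0.0301, 0.446 with an estimated correlation), a list call lost without control replicate 4 (0.293) or sedanolide replicate 1 (0.0677). The Shank1 and Shank3 calls were each lost in 4 of the 19 fits that left out a library, Shank2 in 8 and Syn1 in 9 (adjusted p up to 0.154).

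Some metabolic and clock lists were called after sedanolide with small medians. Pfkfb3 rose by 0.33 (SE 0.09, adjusted p = 0.0365; lost in 6 fits, up to 0.148). It was the only glycolysis entry of 31 called, also adjusted over the list alone (median 0.12, camera adjusted p = 0.028, 0.446 with an estimated correlation; 0.0576 without control replicate 2, 0.0545 without sedanolide replicate 1). Of 19 cold-inducible and circadian genes Per2 and Bhlhe40 (0.57) rose and Cirbp fell (7 and 1 adjusted over the list alone; 0.0266, 0.299 with an estimated correlation; 0.0546, 0.0551 and 0.075 without control replicate 4 and sedanolide replicates 1 and 2). Of 16 homeostatic microglia genes Golm1 rose (0.52; 1 adjusted over the list alone; 0.012, 0.578 with an estimated correlation; 0.177, 0.0546 and 0.0622 without control replicates 1 and 4 and sedanolide replicate 5). Of 22 cholesterol synthesis genes 2 rose, among them Srebf2 at 0.35 (3 adjusted over the list alone; median 0.10, 0.0428, adjusted p = 0.652 with an estimated correlation), and that list call was lost in 6 fits (adjusted p up to 0.955). Its median turned to -0.0373 without control replicate 1, to -0.0692 with the bulb index and to -0.0961 in bulb-poor libraries, so no direction is given for this list.

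The interaction asked whether sedanolide changed genes differently with LPS than without it, and activity-regulated genes differed most clearly. Fos fell by 1.19 after sedanolide alone but rose by 0.93 when sedanolide was added to LPS, a difference of 2.12 (SE 0.28, adjusted p = 0.00105). It stood at 102 CPM ± 27 in controls (n = 4), 45 CPM ± 3.47 with sedanolide, 32 CPM ± 12.5 with LPS and 61 CPM ± 7.14 in co-treated mice (SD, n = 5 each). Egr2 (ENSMUSG00000037868, chromosome 10 from 67371305 to 67378018) differed by 1.90 (SE 0.16, adjusted p = 5.48e-06) and Arc by 1.70 (SE 0.24, 0.00182). Xdh (ENSMUSG00000024066, chromosome 17 from 74190890 to 74257191) differed by -1.91 (SE 0.22, adjusted p = 0.000235), at 4.2 CPM ± 1.06, 8.48 CPM ± 0.739, 10.9 CPM ± 1.96 and 5.85 CPM ± 0.63 in the same order. Of 29 immediate early genes 10 were called, all positive (16 adjusted over the list alone; median 0.79, camera adjusted p = 2.26e-31, and 8.45e-05 with an estimated correlation).

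In all, 104 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 38 positive and 66 negative. The same control libraries enter the interaction and both comparisons with control, so these results are not independent. Of the 38 positive genes, 34 were called lower after LPS and 31 lower after sedanolide alone. Of the 66 negative genes, 64 were called higher after LPS and 31 higher after sedanolide alone. Further positive genes were Ccn1 (2.18, SE 0.37), Dusp1 (1.75), Nr4a1 (1.63), Junb (1.51), Gem (1.41), Btg2 (1.38) and the stress-induced gene Ddit4 (1.24). Negative genes were Plin4 (-2.69, SE 0.47), Emilin2 (-1.92), Hif3a, encoding a hypoxia-inducible factor subunit (-1.91), Myo1g (-1.78), Mmp9 (-1.70), Paqr5 (-1.60), Sox18 (-1.47), Vwf (-1.46), B3gnt3 (-1.46), Fkbp5 (-1.16, SE 0.18) and Slc2a1 (-0.94, SE 0.19, adjusted p = 0.0351). C3 (0.29, SE 0.43, adjusted p = 0.799), C3ar1 (0.13, SE 0.27, 0.862), Lcn2 (-1.83, SE 0.54, 0.129) and Hk2 (-0.34, SE 0.19, 0.409) were not called. Of 25 named calls 13 stayed past the threshold in all 19 fits that left out a library (Ccn1, Fos, Egr2, Dusp1, Arc, Nr4a1, Junb, Ddit4, Plin4, Xdh, Paqr5, Sox18 and Fkbp5), and Slc2a1 lost its call in 10 of them (adjusted p up to 0.0963). Gem (8 fits), Btg2 (15), Emilin2 (11), Hif3a (6), Myo1g (13), Mmp9 (14), Vwf (15) and B3gnt3 (5) were lost in others, with adjusted p up to 0.139.

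The interaction count was 198, 242, 44 and 33 without control replicates 1, 2, 4 and 5, 53, 44 and 40 without LPS replicates 1 to 3, 46, 35 and 38 without sedanolide replicates 3 to 5, and 36, 39, 38, 49 and 163 without co-treated replicates 1 to 5. Bulb-poor libraries gave 20 calls, with Fos at 2.07 (adjusted p = 0.000226), Egr2 at 1.87 (0.000226) and Xdh at -1.90 (0.023) among them, whereas Plin4 (-2.03, 0.262) and Fkbp5 (-1.14, 0.0894) were not called there. With the bulb index in the model 727 genes were called, and upper-quartile scaling turned 38 positive and 66 negative genes into 49 and 39. Of 13 lists called, 5 positive and 8 negative, only immediate early genes held with an estimated correlation, and bulb-poor libraries kept 6.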

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

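The tests of this part were chosen before their values were seen, except the share of calls kept with the bulb index, the bulb-poor and bulb-index medians of immediate early genes in all comparisons, and the splits of all comparisons but the interaction. Of 299 genes lower in co-treated than in LPS libraries, 68.6% had a positive slope on the bulb index within control and sedanolide libraries, against 48.1% of all genes. Of the same 299, 246 (82.3%) were still called lower with the index in the model. Their median log2 change was -0.648 in bulb-poor libraries, against -0.933 in all, though these libraries also served to pick the genes. Bulb tissue may account for a part of this set. The index enters as a straight line on the log scale and follows bulb markers only, so calls kept with it cannot tell how large that part is. Which part of the meningeal and olfactory genes follows dissection could not be told from these libraries.

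The lower ribosomal protein genes after sedanolide (median -0.304) stood at -0.17 with offsets for transcript length and GC content, and oxidative phosphorylation genes moved from -0.176 to -0.0602. A length or GC trend between libraries may therefore make up a part of this shift, and the values cannot tell it from a change in the tissue. With the bulb index in the model the ribosomal median was -0.374, which argues against bulb tissue as its source. Sedanolide replicates 1 and 2 did not share the shift, with scores of -0.09 and -0.022 against -0.351 to -0.511 in replicates 3 to 5.

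Immediate early genes after LPS had a median of -0.664 in bulb-poor libraries and -0.522 with the bulb index (-0.698 in all), and in co-treated against LPS libraries of 0.491 and 0.458 (0.296 in all), so uneven bulb content does not account for these shifts. After sedanolide alone the median went from -0.538 to -0.386 in bulb-poor libraries and -0.299 with the bulb index, so bulb content may make up a part of that fall and of the interaction. Handling or time of collection could also move these genes, and neither is given in the labels.

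The real groups were set among 100 splits, the real one included, which reassigned only libraries of the groups compared. For the interaction, libraries were exchanged only between control and sedanolide and between LPS and co-treated. As many genes were called in 2 splits for LPS against control (1938 genes; highest other 2759, with all 4 libraries of its first group bulb-rich) and in 4 for sedanolide against control (943; 2021, with 3 of 4 bulb-rich). The number was 1 for co-treated against LPS (350; 1), 1 for co-treated against control (1965; 461) and 3 for the interaction (104; 2138, with all 4 bulb-rich). With the bulb index in the model the real groups gave 3433, 1190, 382, 1110 and 727 calls.

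Co-treated replicate 5 stood apart from its group in mitochondrial share (5.5%, others 9.98% to 11.8%) and in the scores of oxidative phosphorylation (-0.236, others 0.121 to 0.182), ribosomal proteins (-0.262, others 0.219 to 0.322), inhibitory neurons (-0.187, others -0.063 to -0.015) and meninges (-0.91, others -0.409 to -0.235). Other scores apart from their group were activated microglia in control replicate 4 (-1.04), interferon (0.261) and striatum (1.06) in LPS replicate 1, cytokines (0.877), neurotrophins (-0.338) and upper layers (-0.232) in LPS replicate 2. Further ones were endothelial identity (0.029) and cold-inducible genes (-0.081) in control replicate 2 and heat shock (-0.1) in sedanolide replicate 5. Such distances were found in 29 of 476 sets, where 23.8 would be found at 1 in 20.

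Single genes apart from their group, in CPM, were Lcn2 at 8.58 in co-treated replicate 2, Itgal at 2.7 and Vwf at 57.2 in co-treated replicate 4, and S100a9 at 19.5, Fos at 54 and Btg2 at 39.3 in LPS replicate 4. LPS replicate 2 had Ldha at 229, Plin4 at 7.54 and Ddit4 at 50.4. Egr2 stood at 15.6 in sedanolide replicate 3, C3ar1 at 4.48 and F13a1 at 4.34 in sedanolide replicate 5, Prg4 at 1.76 in sedanolide replicate 2. Tmem119 stood at 44.4 and Sox18 at 10.1 in control replicate 2.

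The interaction, with 104 genes called, held log2 values of 2.18 (Ccn1), 2.12 (Fos), 1.90 (Egr2), 1.75 (Dusp1), 1.70 (Arc), 1.63 (Nr4a1), 1.51 (Junb), 1.41 (Gem), 1.38 (Btg2), 1.24 (Ddit4), -2.69 (Plin4), -1.92 (Emilin2), -1.91 (Xdh), -1.91 (Hif3a), -1.78 (Myo1g), -1.70 (Mmp9), -1.60 (Paqr5), -1.47 (Sox18), -1.46 (Vwf) and -1.46 (B3gnt3). List medians were 0.786 for immediate early genes (camera adjusted p = 2.26e-31), 0.358 for ribosomal proteins (1.08e-12), 0.328 for oxidative phosphorylation (1.82e-10), 0.283 for interferon (0.00523), 0.208 for cholesterol (0.0107). Negative medians were -0.586 for neutrophils (0.00484), -0.566 for the endothelial LPS response (0.00523), -0.419 for oligodendrocytes (0.0169), -0.394 for their precursors (0.0132), -0.39 for pericytes (0.0186), -0.386 for endothelial identity (4.21e-08), -0.253 for homeostatic microglia (0.049) and -0.219 for reactive astrocytes (0.0416). The interaction correlated with transcript length (Spearman -0.319) and GC content (-0.412) across genes, so the ribosomal and oxidative phosphorylation medians may follow these trends in part. All but the first had adjusted p = 0.602 to 0.691 with an estimated correlation.

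Of these 13 interaction lists 8 lost their call when a library was left out. Homeostatic microglia lost it in 9 of 19 fits (adjusted p up to 0.331), reactive astrocytes in 5 (0.616), oligodendrocytes in 4 (0.28), pericytes in 4 (0.152), oligodendrocyte precursors in 2 (0.0904), cholesterol in 2 (0.226), interferon in 1 (0.321) and the endothelial LPS response in 1 (0.0738). Neutrophils kept their call, with a median of -1.01 to -0.294 over these fits. Bulb-poor libraries did not call 7 of the 13: homeostatic microglia (-0.211, adjusted p = 0.0888), reactive astrocytes (0.0736, 0.29), interferon (0.119, 0.493), the endothelial LPS response (-0.296, 0.127), oligodendrocytes (0.138, 0.524), their precursors (-0.0567, 0.489) and pericytes (-0.0403, 0.558).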

How the results depend on the processing

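Genes called in LPS against control (1938) numbered 1180 at a minimum fold of 1.5, 4503 with limma-voom, 1114 with only the groups compared, 848 and 761 in bulb-poor and bulb-rich libraries. They numbered 3433 with the bulb index (3878 with length and GC offsets as well). Leaving out a library gave 1308 (control replicate 5) to 2478 (control replicate 2). For sedanolide against control (943) the counts were 317 at a fold of 1.5, 439 without a filter, 1892 with DESeq2, 4399 with limma-voom, 19 with only the groups compared. They were 8 in bulb-poor and 0 in bulb-rich libraries, 253 with offsets (363 with the bulb index too), and 97 (control replicate 5) to 1410 (control replicate 4) with a library left out. For co-treated against LPS (350) they were 912 with DESeq2, 2647 with limma-voom, 723 with only the groups compared, 35 in bulb-poor libraries, 543 with offsets (727 with the bulb index too), and 141 (LPS replicate 2) to 590 (LPS replicate 5). For co-treated against control (1965) they were 1068 at a fold of 1.5, 1244 without a filter, 4784 with limma-voom, 1110 with the bulb index (1046 with offsets too), 615 in bulb-poor libraries, and 876 (control replicate 5) to 2907 (control replicate 2). For the interaction (104) they were 447 with DESeq2, 3836 with limma-voom, 727 with the bulb index (293 with offsets too), 20 in bulb-poor libraries, and 33 (control replicate 5) to 242 (control replicate 2). The share of opposite signs (85.7%) was 90.2% at a fold of 1.5, 94.8% in bulb-poor libraries and 80.2% with the LPS libraries split, and 78.9% (control replicate 2) to 90% (control replicate 1) with a library left out.

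Replicate number as a block, a pairing the labels do not state, gave 95 genes for sedanolide (133 with the bulb index), 145 for co-treated against LPS (209), 954 for co-treated against control (631) and 32 for the interaction, and 88.7% opposite signs. Values that changed sign included Cspg5 after LPS (-0.231, offsets and bulb index), Prg4 in co-treated against LPS (0.0339, bulb-poor), and several list medians. After LPS this was glycolysis (0.0253), at -0.0115 without control replicate 2, -0.0727 with offsets and -0.0917 with the bulb index too. After sedanolide they were homeostatic microglia (-0.00442, bulb-poor), olfactory areas (0.0617, offsets and bulb index), mitochondrially encoded genes (0.319, offsets), oligodendrocytes (-0.432, bulb-poor) and cholesterol synthesis. The last stood at -0.0692 with the bulb index, -0.0961 bulb-poor, -0.0893 with offsets and bulb index, -0.0503 with block and bulb index, -0.0373 without control replicate 1, and 0.0991 with a test direction reversed by the bulb index and an estimated correlation. In co-treated against LPS they were mitochondrially encoded genes (-0.164, offsets and bulb index), homeostatic microglia (-0.128, adjusted p = 0.0343) and meninges (0.21, both bulb-poor). In the interaction they were mitochondrially encoded genes (-0.326 with offsets, -0.28 with the bulb index too), reactive astrocytes (0.0736) and oligodendrocytes (0.138, both bulb-poor). Offsets turned 568 higher and 375 lower genes after sedanolide into 111 and 142, 51 and 299 in co-treated against LPS into 191 and 352, and 38 and 66 in the interaction into 42 and 40. The cause of these changes was not tested. In simulations 11% of 1.5-fold and 67.5% of 2-fold interactions were recovered, so weaker ones could be missed at this size of groups.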

Other observations

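Plin4, Hif3a and Fkbp5, picked here after their values were seen, were higher after LPS than in controls, with log2 changes of 1.56 for Plin4 (SE 0.34, adjusted p = 0.00398), 1.20 for Hif3a (SE 0.27, 0.0051) and 1.04 for Fkbp5 (SE 0.14, 1.73e-05). They were lower in co-treated than in LPS mice (adjusted p = 0.0087, 0.0432 and 0.00422), while the list of 22 glucocorticoid-responsive genes was not called there (camera adjusted p = 0.0793). Plin4 (ENSMUSG00000002831) stood at 1.27 CPM ± 0.477 in controls (SD, n = 4), 3.76 CPM ± 2.19 with LPS, 2.57 CPM ± 0.589 with sedanolide and 1.17 CPM ± 0.288 in co-treated mice (n = 5 each), and LPS replicate 2 raised its LPS mean (7.54 CPM, others 2.04 to 3.57). In the same order Hif3a stood at 2.95 CPM ± 0.659, 6.8 CPM ± 2.38, 5.53 CPM ± 1.7 and 3.4 CPM ± 0.736, and Fkbp5 at 27.4 CPM ± 3.4, 56.5 CPM ± 11.2, 36.9 CPM ± 5 and 33.9 CPM ± 3.11. After sedanolide alone none of the 3 passed the test, with log2 changes of 1.01 for Plin4 (SE 0.34, adjusted p = 0.0834), 0.90 for Hif3a (SE 0.27, 0.0559) and 0.43 for Fkbp5 (SE 0.13, 0.0642). Zbtb16 (ENSMUSG00000066687) was higher than in controls with LPS, with sedanolide and with both, and its rise with both (0.63, SE 0.16, adjusted p = 0.0145) was the smallest of the 3.

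Saa3 and Ccl5, the genes of largest rise after LPS, did not pass the test between co-treated and LPS mice. Saa3 stood at 139 CPM ± 20.1 in co-treated and 139 CPM ± 40.1 in LPS mice (SD, n = 5 each; adjusted p = 0.991), and Ccl5 at 25.6 CPM ± 7.47 and 20.8 CPM ± 9.97 (0.544). The log2 ratio of C3 to C3ar1, chosen after the values were seen, was -0.321 ± 0.344 with LPS and -1.37 ± 0.456 in co-treated mice, a difference of -1.05 (exact permutation p = 0.016, smallest possible 0.0079). It was -2.1 ± 1.26 in controls, 1.78 below LPS (exact permutation p = 0.016, the smallest possible), and -3.44 ± 1.16 with sedanolide (difference -1.33, exact permutation p = 0.15).

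The spread between libraries, as a common biological coefficient of variation, was 0.262 in controls, 0.205 with LPS, 0.186 with sedanolide and 0.105 in co-treated mice. In bulb-poor libraries it was 0.151 (n = 2), 0.147 (n = 2) and 0.116 (n = 3), and 3 of the 5 co-treated libraries gave 0.0468 to 0.145.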
